A study of Mus musculus with 10 samples.

How the data were processed

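Total RNA was taken from whole liver of 10 mice, 5 given phenobarbital at 0.05% (w/v) in drinking water for 28 days and 5 controls, per the labels' protocols. RNA was extracted with TRIzol and silica columns, and 0.1 µg was reverse transcribed from an oligo(dT) primer with a T7 promoter, transcribed in vitro with biotin and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The 3' IVT labelling reads the 3' end of polyadenylated RNA, so probe sets far from that end depend on RNA integrity and on the length of the labelled product. Per the submitters' processing notes GCOS, the array software, was used, with no version given. The authors deposited log2 expression values, 1 per probe set and array, from 2.34 to 15.13 with 2 decimals. That the scale is log2 was read from this range. The method of summarising and normalising the probes is not given in the sources used here. No quartile differed between arrays by more than 0.16, under the limit of 0.3 set for renormalising, so the values were used as deposited. The groups and replicate numbers came from the labels, each array is a separate animal, all 10 columns were used, and no arrays were identical (the highest correlation between arrays over all genes was 0.997).

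Of 45101 probe sets, 64 were controls, 34945 had a single gene symbol in the platform annotation, 932 had several symbols, and 9160 were not listed there and stay unnamed here, not counting the controls. Symbols were compared by Entrez ID with the RefSeq gene table of GRCm38.p6 for 34754 probe sets, which was used for names alone, and none needed changing. Coordinates are not reported, since no build is stated for the arrays. Each of 18193 genes was represented by its probe set with the highest mean over all 10 arrays; 9010 genes had more than 1. Low probe sets were kept, and a value near the bottom of the scale is close to background, where fold changes are understated.

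Phenobarbital was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg over genes, adjusted p under 0.05, with a log2 change of 1 for the 2-fold counts). The 37 gene lists, 25 on function or condition and 12 on cell types, were tested with camera at a preset correlation of 0.01, adjusted over all lists; of 945 listed members 826 were measured, and the others are not analysed here. The estimated correlation and fry, which tests a list's genes on their own, were alternatives. The lists, the design, the first alternatives and the rule for naming genes were set before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 called members per list with the largest change (or the 2 with the smallest p), and 16 genes fixed by name, and gave 138 genes, of which the text names a part. Array measures were compared by an exact two-sided permutation test, whose smallest p with 5 against 5 is 0.00794. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

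The arrays split by the largest gap in their mean poly-A spike-in value into 4 and 6. This split, called the labelling batch, was entered as a block, and the spike-in mean as a covariate, both as alternatives chosen after seeing the data. The alternatives set beforehand were quantile normalisation, median centring, the brighter genes alone, the mean of a gene's probe sets, probe sets that match a single transcript, all probe sets singly, trend and robust variance, array weights, the replicate number as a block, and leaving out each animal. Pseudocount alternatives did not apply to log2 values.

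The fit was tested on simulated data of 18193 genes with 200 changed, 5 runs of the comparison of 5 against 5. The cell cycle list was raised as well and left out of the false calls. The fit recovered 100% of 4-fold, 97.2% of 2-fold and 78.8% of 1.4-fold changes with 10.6 false calls a run. A batch effect was then added to every gene on the arrays with high spike-ins. The false calls rose to 1557.6 without a block and were 4.8 with it, and the block recovered 100%, 79.0% and 25.5% of the changes. The size of this effect was set by hand, so 1557.6 does not estimate the batch calls in these data.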

Results

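Gene expression was measured in the livers of 10 male B6C3F1/Crl mice, a hybrid strain used in carcinogenicity studies. The animals were 29 to 32 days old on receipt, had 5 days to settle, and were divided at random into 2 groups of 5. One group drank water with 0.05% (w/v) phenobarbital for 28 days, and the other served as control. Phenobarbital is a barbiturate that promotes liver tumours in rodents without damaging DNA, and the series title places the comparison in a study of 5-hydroxymethylcytosine in liver. The question was which liver transcripts differed between treated and control animals. Each animal's liver RNA was hybridised to its own Affymetrix mouse array, and the deposited value is a log2 expression level for each of 45101 probe sets. Array medians lay between 5.42 and 5.50, no quartile differed by more than 0.16 between arrays, and the number of arrays (n = 5 per group) limits the precision.

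The arrays fell into 2 sets on their poly-A spike-ins. The mean of the 24 poly-A spike-in probe sets, bacterial transcripts added to the RNA before labelling, was between 7.77 and 8.64 on control replicates 1, 2, 3 and 5. It was 6.40 on control replicate 4 and between 5.76 and 6.58 on the 5 phenobarbital arrays. Beta-actin, which has separate probe sets at its 3' and 5' ends, gave a 3' minus 5' difference of 1.54 ± 0.18 (SD, n = 5) in controls, 1.28 on control replicate 4 alone, and 1.25 ± 0.06 (SD, n = 5) in treated animals (two-sided exact permutation p = 0.0238, Benjamini-Hochberg 0.0278 over 7 array measures). Not every measure placed control replicate 4 with the treated arrays. The 3' minus 5' difference of Gapdh separated all controls (-0.15 to -0.03, -0.15 on control replicate 4) from all treated arrays (-0.28 to -0.21), and so did the upper quartile (7.39 to 7.46, 7.41 on control replicate 4, against 7.30 to 7.36; exact permutation p = 0.00794 each, Benjamini-Hochberg 0.0278). The cause of these differences was not tested, and the batch as a block does not remove them. Hybridisation spike-ins, which are added after labelling, split the arrays the same way (10.95 to 11.30 on control replicates 1, 2, 3 and 5, 10.65 on control replicate 4, 10.54 to 10.74 on treated arrays; Benjamini-Hochberg 0.0317), so the split is not shown to come from labelling alone. Probe sets of 18S ribosomal RNA averaged 13.96 in controls, 13.68 on control replicate 4 and 13.35 in treated animals (Benjamini-Hochberg 0.0278). The spike-in set is called the labelling batch here for short, although no label names one and the labels give a single labelling kit lot for all 10 arrays. The high set held controls alone and gives no comparison, so the within-batch value of a gene is the mean of the 5 treated arrays minus control replicate 4, fitted with the batch as a block. The block was added after the data were seen, and it leaves the batch and the animal of control replicate 4 inseparable. Gene lists tested with the block rest on that control as well, so their p-values do not measure how far control animals differ.

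**Figure D1:**
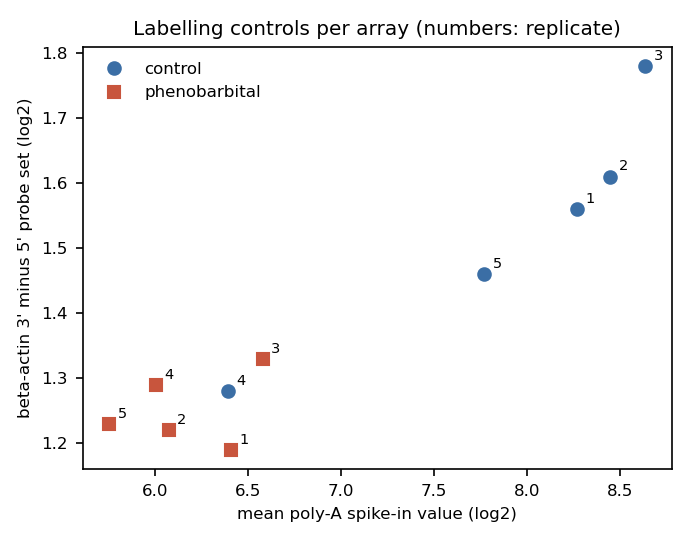
Mean poly-A spike-in value (x axis, log2) against the beta-actin 3' minus 5' difference (y axis, log2) for each array, with points numbered by replicate. Control replicate 4 lies at 6.40 and 1.28, among the 5 phenobarbital arrays, and the other 4 controls lie at 7.77 or above and 1.46 or above.

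Phenobarbital changed the liver transcriptome, with the largest rises among enzymes that metabolise drugs. Cyp2b10, the classical phenobarbital-inducible cytochrome P450, was 133-fold higher (log2 fold change 7.05 ± 0.24 SE), going from 6.47 ± 0.66 to 13.52 ± 0.04 (SD, n = 5 each). Cyp2c55 was 17.7-fold higher. Cyp2c65 went from 4.12 ± 0.16, below the lower quartile of every array and not shown to be above background, to 10.98 ± 0.13 (SD, n = 5), so its 116-fold rise may be understated. The largest falls were Csad, which makes the taurine precursor hypotaurine (log2 fold change -2.06 ± 0.22 SE), and Il6ra, the interleukin-6 receptor alpha chain (-1.90 ± 0.16 SE). In these 5 genes every treated animal lay outside the range of the controls, and the limma adjusted p was between 1.64e-14 and 9.49e-05.

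Of 18193 genes tested with limma, 3692 (20.3%) passed an adjusted p of 0.05, 1641 higher and 2051 lower in treated livers. Most changes were small: the median absolute log2 fold change of the called genes was 0.358, and 3583 of them changed less than 2-fold. At least 2-fold, 69 genes were higher and 40 lower. The groups did not overlap in 12.9% of genes, where chance gives 0.794%. With the labelling batch as a block, 143 genes passed, 88 higher and 55 lower, and 124 of them were also called, in the same direction, without it. Of the genes at least 2-fold higher, 47 of 69 also passed with the block, against 8 of the 40 at least 2-fold lower. The share of higher calls was 44.4% on the deposited scale, 60.0% after quantile normalisation, 58.8% after median centring and 31.8% among the brighter genes, so the balance of rises and falls depends on these choices. Leaving out control replicate 2 or phenobarbital replicate 2 reduced the calls to 2460 and 2431.

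**Figure D2:**
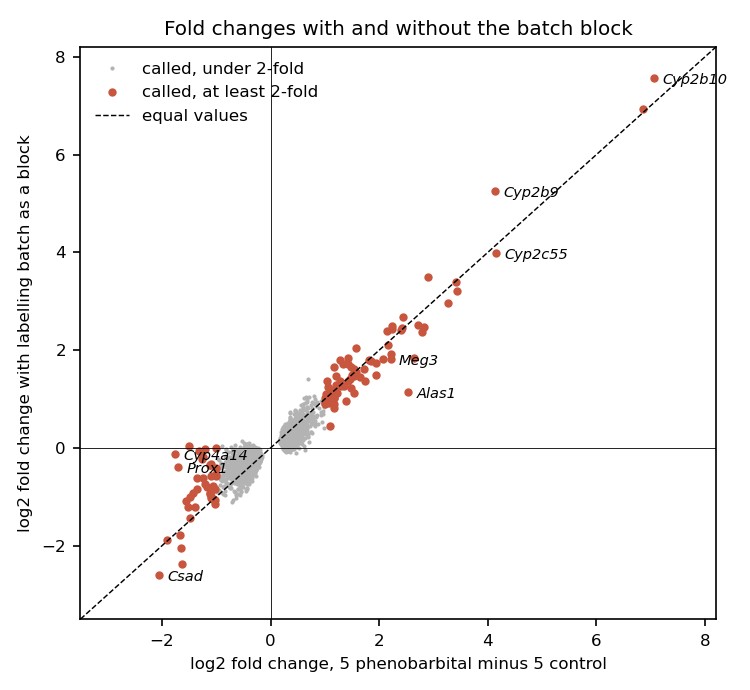
Log2 fold change of each called gene between 5 phenobarbital and 5 control animals (x axis) against its value with the labelling batch as a block (y axis); red points changed at least 2-fold and the dashed line marks equal values. Cyp2b10 (7.05 and 7.57) and Csad (-2.06 and -2.60) lie near or beyond the line, and Alas1 (2.53 and 1.14), Prox1 (-1.70 and -0.39) and Cyp4a14 (-1.77 and -0.13) lie nearer 0 with the block.

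Cytochrome P450 enzymes of families 1 to 3, which oxidise drugs and steroids, rose as a group. Of 37 measured members 17 were higher and 4 lower over all genes, 18 and 6 adjusted over the list alone, and camera gave the list an adjusted p of 2.2e-06. It was the only list whose call held with an estimated correlation (adjusted p = 0.0482). Cyp2b10, Cyp2c65, Cyp2c55 and Cyp2b9 (log2 fold changes 7.05, 6.86, 4.15 and 4.14) rose most, with within-batch values of 7.57, 6.92, 3.99 and 5.26 that all passed. Their paralogs are similar in sequence, and the Cyp2c65 probe set is of a type that can match several transcripts. Cyp3a11, a target of the pregnane X receptor, started near the top of the scale in controls (14.43 ± 0.05 SD, n = 5) and stood at 14.58 ± 0.02 in treated animals (limma adjusted p = 0.0633), and passed after median centring (0.19), among the brighter genes, with the mean of probe sets and with trend and robust variance. With the batch as a block the list's camera adjusted p was 1.8e-09.

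Conjugating enzymes, which attach glutathione, sulphate or glucuronic acid to drugs, rose in 23 of 49 measured members and fell in none over all genes, or 25 and 3 adjusted over the list alone (camera adjusted p = 2.2e-07, lost at an adjusted p = 0.0632 with an estimated correlation). The largest rises were in glutathione transferases. Gstm3 went from 11.05 ± 0.28 to 13.83 ± 0.09 (SD, n = 5), a log2 fold change of 2.78 (2.36 within the batch). Gstt3 rose by 2.71 (2.51) and Gstm2 by 1.73 (1.37), and both kept their call within the batch. The sulphotransferase Sult3a1 rose by 1.42 (1.84, limma adjusted p = 0.0766 within the batch). Targets of NRF2, the transcription factor of the oxidative stress response, rose in 10 of 21 measured members and fell in 1, with 12 and 1 adjusted over the list alone (camera adjusted p = 8.3e-06, lost at an adjusted p = 0.193 with an estimated correlation). Gstm1 rose by 0.97, Srxn1 by 0.78, Nqo1 by 0.76 and Gsta4 by 0.68, with within-batch values of 0.76, 0.74, 0.68 and 0.63, of which Gstm1 passed. Gstm1 and Gsta4 also belong to the conjugating enzymes, and other members to the oxidases and hydrolases, so the NRF2 shift is not independent of those lists. With the batch as a block both lists passed camera, at adjusted p of 3.7e-11 and 2.9e-06 (adjusted p = 0.0478 and 0.18 with an estimated correlation, so that of NRF2 did not hold there).

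Other drug-handling lists held members that moved both ways and did not pass camera. Oxidases and hydrolases had 11 members higher and 4 lower of 38, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.132, but 0.0353 without phenobarbital replicate 5 and 0.0226 among the brighter genes). With the batch as a block the list passed camera (adjusted p = 0.00921) with a median log2 fold change of 0.004 against 0.05 without, and not with an estimated correlation (adjusted p = 0.657). Among them the carboxylesterase Ces2a rose by 1.17 (1.01 within the batch), the epoxide hydrolase Ephx1 by 0.65 (0.45) and the oxygenase Fmo5 by 0.50 (0.50), and the aldehyde oxidase Aox3 fell, with a log2 fold change of -0.63 (-0.71), and of these 4 Ces2a and Aox3 passed within the batch. Bile and drug transporters had 5 higher and 6 lower of 24, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.827). The efflux pumps Abcc4 and Abcc3 rose by 2.15 (2.40) and 0.84 (0.86), the uptake carrier Slco1a1 fell (-0.49, -0.38 within the batch), and of these 3 the pumps passed within the batch. P450 electron transfer and haem synthesis had 4 members higher and 1 lower of 15, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.203). Alas1, the rate-limiting enzyme of haem synthesis, rose by 2.53 and had a within-batch value of 1.14 (limma adjusted p = 0.36), since control replicate 4 lay at 10.72 and the other controls between 8.78 and 9.14.

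**Figure D3:**
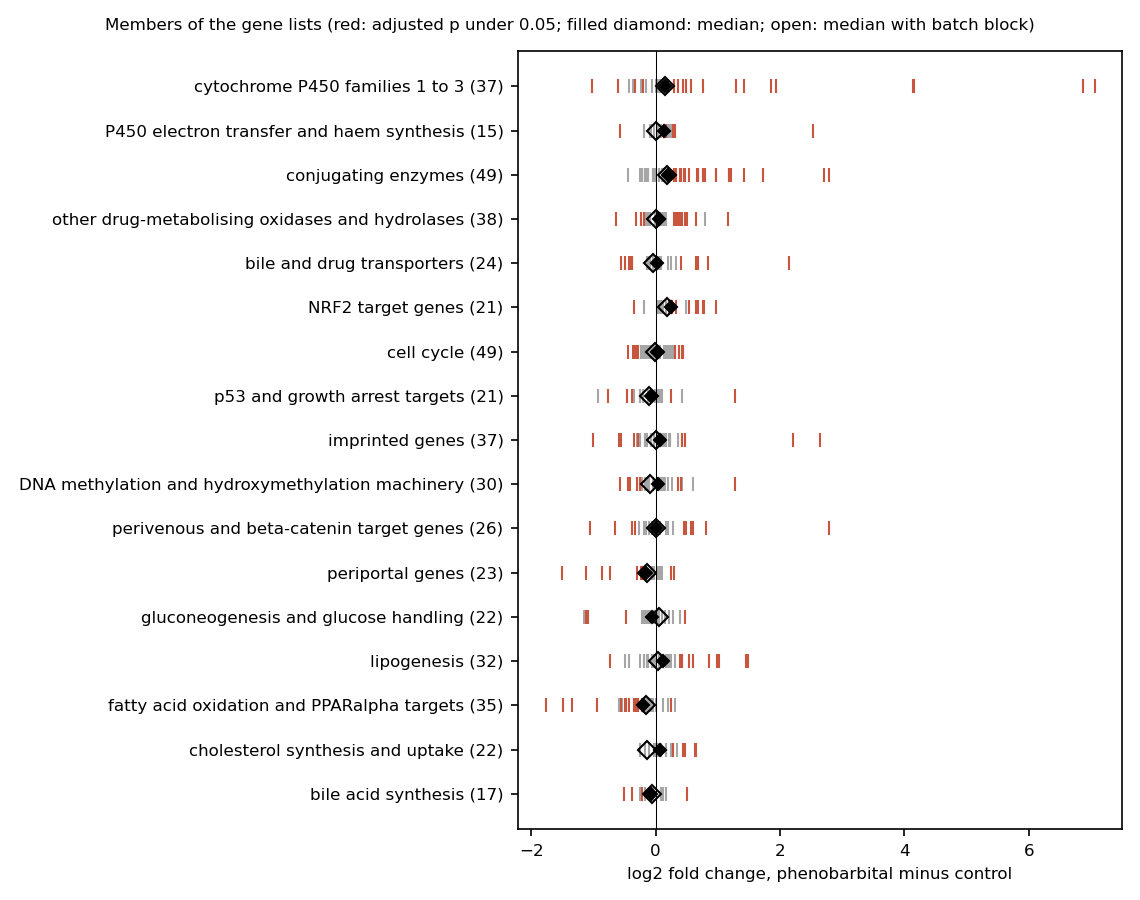
Log2 fold change (x axis, phenobarbital minus control) of each measured member of the gene lists (rows, with the number measured); red marks passed an adjusted p of 0.05, and diamonds give the list median without (filled) and with (open) the batch block. Cytochrome P450 members reach 7.05, conjugating enzymes 2.78, and the median of fatty acid oxidation genes lies at -0.20 (-0.16 with the block).

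Among genes listed as imprinted, which are expressed from the copy of a single parent in some or all tissues, the non-coding RNAs Meg3 and Rian of the Dlk1-Dio3 cluster rose. Rian went from 5.71 ± 0.48 to 8.35 ± 0.42 and Meg3 from 8.46 ± 0.30 to 10.67 ± 0.23 (SD, n = 5 each). Their log2 fold changes were 2.64 ± 0.23 and 2.21 ± 0.14 (SE), both 1.83 within the batch, where both passed limma (adjusted p = 0.014 and 0.00171). Tested singly, 8 of 11 probe sets of Meg3 and 2 of 4 of Rian were called, all higher. Ube3a, a ubiquitin ligase gene, fell from 9.63 ± 0.34 to 8.63 ± 0.47 (SD, n = 5) and Ppp1r9a from 6.83 ± 0.17 to 6.25 ± 0.16, with within-batch values of -0.54 and -0.38 that did not pass. Tested singly, 2 of 6 probe sets of Ube3a and 1 of 5 of Ppp1r9a were called lower. Whether these genes are imprinted in liver was not tested. Of 37 measured imprinted genes 6 were higher and 5 lower, 9 and 6 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.331).

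Among genes that write, oxidise and read DNA methylation, 3 of 30 measured members were higher and 5 lower, the same numbers as adjusted over the list alone. The median and mean log2 fold change were both 0.04, while camera ranked the list slightly downward (adjusted p = 0.975). The median was -0.09 with the batch as a block and 0.015 to 0.057 with 1 animal left out. Tet1, a 5-methylcytosine dioxygenase near the bottom of the scale, rose from 4.76 ± 0.20 to 5.17 ± 0.11 (SD, n = 5; limma adjusted p = 0.011), on 1 of its 4 probe sets. Its within-batch value was 0.33 (limma adjusted p = 0.431), and the call was also lost with the mean of its probe sets (0.14) and on a single-transcript probe set (0.12). The log2 fold changes of Tet2 and Tet3 were -0.16 ± 0.07 and 0.05 ± 0.09 (SE), and those of the methyltransferases Dnmt1 and Dnmt3b 0.02 ± 0.09 and -0.21 ± 0.09 (SE), none passing limma (adjusted p between 0.115 and 0.909). Dnmt3a fell (-0.44, with 4 of 5 probe sets lower), a call lost within the batch (-0.20) and without control replicate 3 (-0.40, limma adjusted p = 0.0517). The methyl-CpG binding protein gene Zbtb38 fell (-0.57), a call lost within the batch (-0.39, limma adjusted p = 0.421). Gadd45b, a stress-inducible gene linked to DNA demethylation, rose by 1.28 ± 0.18 (SE, limma adjusted p = 0.000832) and by 1.81 within the batch, passing limma in both. The larger within-batch value rests on control replicate 4, which lay at 6.50 against 7.10 to 7.29 in the other controls.

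**Figure D4:**
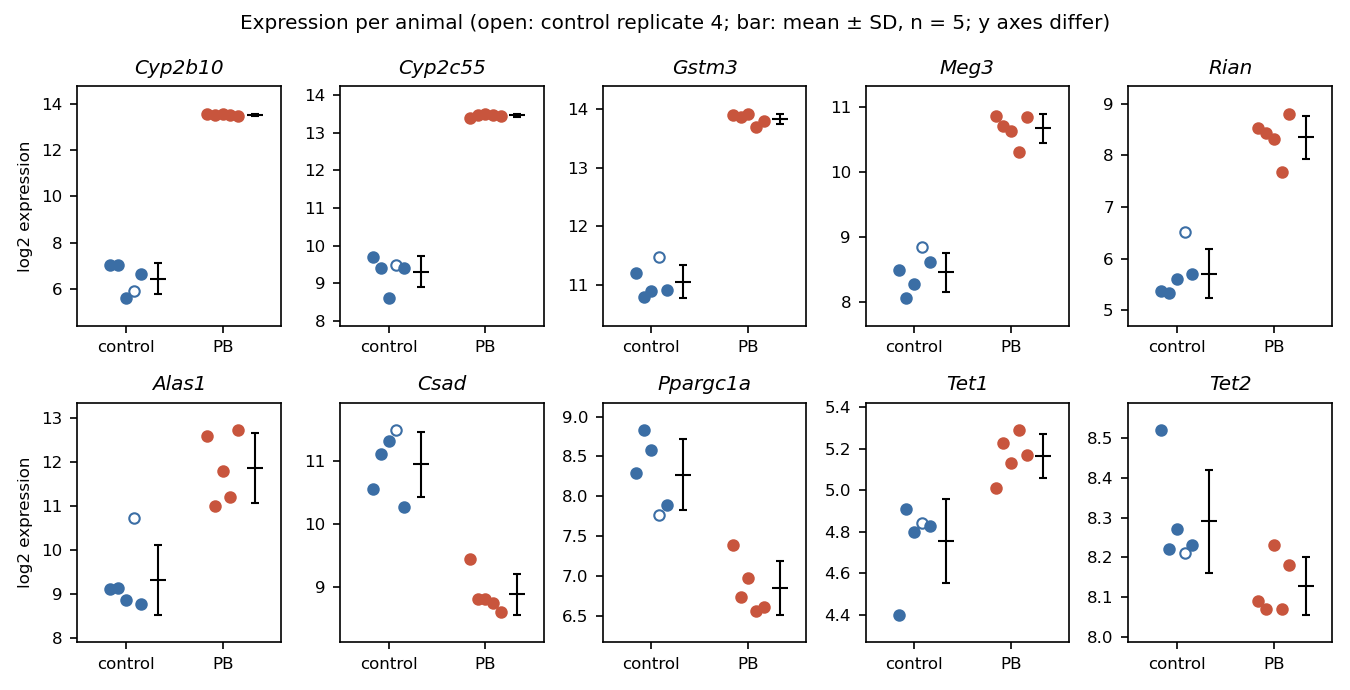
Log2 expression (y axes, which differ in range) of 10 genes in each of 5 control and 5 phenobarbital (PB) animals; the bar is the mean ± SD (n = 5) and the open point is control replicate 4. Treated values of Cyp2b10 lie near 13.52 and control values near 6.47, and the Alas1 value of control replicate 4 (10.72) lies between the groups.

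Fatty acid oxidation genes and targets of PPARalpha, the fasting-activated regulator of lipid use, were lower as a group by camera. Of 35 measured members 16 were lower and 1 higher, over all genes and adjusted over the list alone (camera adjusted p = 6.2e-06, median log2 fold change -0.20). The call was lost with an estimated correlation (adjusted p = 0.679) and with the batch as a block (median -0.16, camera adjusted p = 0.0769) or the spike-in covariate (0.242). With the block none of the 16 lower members was called by limma and 3 had an unadjusted p under 0.05. The list's mean level lay between 10.16 and 10.36 in the treated animals and between 10.43 and 10.96 in controls. The value of 10.96 was that of control replicate 2, and the other controls reached at most 10.60. Cyp4a14 had a log2 fold change of -1.77 ± 0.49 (SE), Angptl4 of -1.48 ± 0.31, the acyl-CoA thioesterase Acot1 of -1.35 ± 0.27 and Cyp4a31 of -0.94 ± 0.25. All 4 were highest in control replicate 2, as with 9.83 for Cyp4a14 against 6.01 to 7.81 in the other controls. Without that animal the log2 fold changes were -1.22, -1.17, -1.09 and -0.65 in the order given, and the calls held. Cyp4a14 and Cyp4a31 lost their call without control replicate 3 (-1.73 and -0.92), Cyp4a31 also without phenobarbital replicate 2 (-0.89) and with the mean of its probe sets (-0.77), Cyp4a14 also with trend and robust variance, and Angptl4 on its single-transcript probe set (-0.05). The within-batch values were -0.13 for Cyp4a14, -0.998 for Angptl4, -0.83 for Acot1 and -0.63 for Cyp4a31, none passing. Ppara itself and its coactivators Ppargc1a and Ppargc1b fell, with log2 fold changes of -0.87, -1.42 and -0.87 (-0.52, -0.92 and -0.81 within the batch, none passing). In their list of nuclear receptors and coregulators, 7 of 33 members were lower and none higher, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.251, fry 0.0296). Nr1i3, the constitutive androstane receptor through which phenobarbital acts, had a log2 fold change of -0.26 ± 0.10 (SE, limma adjusted p = 0.0771).

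Among lipogenesis genes, 10 of 32 measured members were higher and 1 lower, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0518). It passed without control replicate 1, 2 or 5 or phenobarbital replicate 1 or 5 (adjusted p between 0.0152 and 0.0485). With the batch as a block it passed camera (adjusted p = 0.0275), with a median of 0.04 against 0.13 without, and not with an estimated correlation (adjusted p = 0.657). Thrsp, a regulator of lipogenesis, rose by 1.49, Pnpla3 by 1.46, the elongase Elovl6 by 1.01 and fatty acid synthase Fasn by 0.98, and none passed within the batch (1.22 for Thrsp, 1.402 for Pnpla3, 1.11 for Elovl6 and 0.84 for Fasn). Fasn lost its call without phenobarbital replicate 2 (0.88, limma adjusted p = 0.0517) and with trend and robust variance. Cholesterol synthesis had 5 of 22 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.173, but 0.0193 without phenobarbital replicate 5, where the median was 0.14). The list's direction turned with the batch as a block (median -0.13, camera adjusted p = 0.595), and 12 of 22 members kept their sign. Its member Sqle rose by 0.64 (0.29 within the batch, not passing), while Mvd and Fdps, called higher at 0.63 and 0.47, had within-batch values of -0.03 and -0.10. Mvd lost its call in 7 and Fdps in 8 of 10 omissions of a single animal, with values over the 10 omissions from 0.49 to 0.80 and from 0.40 to 0.62. Bile acid synthesis had 1 higher and 3 lower of 17 by both adjustments (camera adjusted p = 0.331), and Cyp7a1, its rate-limiting enzyme, stood at 9.62 ± 0.42 in controls and 9.70 ± 0.47 in treated animals (SD, n = 5; limma adjusted p = 0.831).

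Periportal genes, active near the portal vein, fell in 8 of 23 measured members and rose in 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0139). The list's call was lost with an estimated correlation (adjusted p = 0.526), with the mean of probe sets, among the brighter genes and with the batch as a block or the spike-in covariate (camera adjusted p = 0.0639 and 0.0623), while its median of -0.16 stayed between -0.16 and -0.13. The gluconeogenic enzyme Pck1 had a log2 fold change of -1.11 ± 0.23 (SE), Etnppl of -0.86 and Hsd17b6 of -0.73, with within-batch values of -0.92, -0.77 and -0.72 that did not pass, and Etnppl lost its call with the mean of its probe sets (-0.55). Ass1, of the urea cycle, had -1.50 over all animals and 0.04 within the batch. Gluconeogenesis and glucose handling had 1 higher and 3 lower of 22 by both adjustments (camera adjusted p = 0.428), with Irs2, an insulin receptor substrate, at -1.09 (-0.82 within the batch, not passing). Perivenous and beta-catenin target genes moved both ways, 6 higher and 4 lower of 26, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.589). Among them the ammonium transporter Rhbg rose by 0.81 (0.66 within the batch, limma adjusted p = 0.134) and Gstm3 by 2.78, and the receptor Lgr5 fell (-1.05, -1.07 within the batch) on 1 of its 2 probe sets while the other rose.

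Cell cycle genes had 4 members higher and 5 lower of 49 by both adjustments (camera adjusted p = 0.656). The replication helicase gene Mcm2 rose by 0.38, the centromere gene Cenpa fell (-0.44, lost with the mean of its probe sets, -0.21), neither passing within the batch (0.43 and -0.41), and the proliferation marker Mki67 stood at 4.92 ± 0.11 in controls and 5.12 ± 0.28 in treated animals (SD, n = 5; limma adjusted p = 0.232). Targets of p53 had 2 higher and 3 lower of 21 by both adjustments (camera adjusted p = 0.331). Gadd45b belongs to this list too, and Trp53inp1 fell (-0.77), a call lost within the batch (-0.36, limma adjusted p = 0.624).

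The 12 largest rises included genes outside these lists. Nebl, an actin-binding protein gene, rose by 3.42 ± 0.12 (SE), the pancreatic lipase-related gene Pnliprp1 by 3.27 ± 0.16, Gm10419 by 3.43 ± 0.18 and 1700067K01Rik by 2.83 ± 0.17, and all 4 kept their call within the batch. Cyp26a1, which degrades retinoic acid, rose by 2.89 ± 0.42 (3.49 within the batch, limma adjusted p = 0.0529, and 3.89 with the spike-in covariate, 0.0227). Of the 12 largest falls, Csad, Il6ra, Enho, Dnase2a, Dnaic1 and Rdh16f2 kept their call, with within-batch values between -1.43 and -2.60, though Dnase2a lost its call with the spike-in covariate (-1.65 against -1.64 without, limma adjusted p = 0.112). Prox1, Serpina7, Pde5a, Angptl4, Ppargc1a and Hectd2os lost it, with log2 fold changes down to -1.70 over all animals and between -0.39 and -1.21 within the batch. Hectd2os, a non-coding RNA gene, fell from 8.22 ± 0.42 to 6.82 ± 0.31 (SD, n = 5).

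Among markers of liver cell types, stellate cell and matrix markers were lower in 8 and higher in none of 21 (camera adjusted p = 0.00988), or 9 lower and 1 higher adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.679) and without control replicate 4 (camera adjusted p = 0.0549). Examples were Lrat (-0.86), which stores retinol, and the growth factor receptor gene Pdgfrb (-0.67, and -0.23 without a call on a single-transcript probe set), neither passing within the batch (-0.66 and -0.57). Sinusoidal endothelial markers were lower in 9 and higher in none of 18 by both adjustments (camera adjusted p = 0.00428), with Bmp2 at -0.78, a call lost within the batch (-0.37, limma adjusted p = 0.588), and Wnt2 at -0.49, which kept its call (-0.70, limma adjusted p = 0.0164). The sinusoidal call was lost with an estimated correlation (adjusted p = 0.679), with the spike-in covariate (median -0.17 against -0.19, camera adjusted p = 0.0614) and with fry (0.0561). With the batch as a block it passed camera but not with an estimated correlation, and the stellate list likewise (median -0.40 against -0.18 without the block). The block rests on control replicate 4, whose stellate list mean of 8.16 was the highest of all 10 arrays. Hepatocyte markers had 1 member lower of 14 over all genes and none adjusted over the list alone (camera adjusted p = 0.343, fry 0.0149). Albumin, the main hepatocyte product, differed by -0.02 ± 0.05 (SE), but lay near the top of the scale (mean 14.98 in controls), where a difference may not show. Macrophage and Kupffer cell markers had 2 lower of 17 by both adjustments (camera adjusted p = 0.203), among them the scavenger receptor Cd163 (-0.73, with -0.82 and a limma adjusted p of 0.121 within the batch). That list passed without control replicate 3 or phenobarbital replicate 2 (camera adjusted p = 0.0258 and 0.0337). It also passed with the batch as a block, though not with an estimated correlation there. Its mean on control replicate 4 was the highest of all arrays (8.38, with 8.37 on control replicate 2).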

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

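The checks for outlying animals and of probe sets without a single symbol followed rules set before the data were examined, and the within-batch value was added after. The groups tested for outlying animals were those of the genes named by the rule and of the array measures. The gap between the most extreme animal and its nearest neighbour was set against the group's range. It took up more than 0.71 of that range in 13 of 290 such groups of 5 animals. Chance gives this in about 1 of 20 groups of unselected values. Most of the genes were named for a called change, and several cases fall on the same animal. The number therefore does not show whether single cases are chance. Phenobarbital replicate 1 stood highest for the heat shock gene Hspa1a (11.50 against at most 9.37 in the other treated animals, ratio 0.852), its co-chaperone Dnajb1 (11.91 against 9.95 to 10.07, 0.939), the immediate-early gene Jun (10.50 against 7.42 to 8.02, 0.805) and Csad (9.45 against 8.61 to 8.82, 0.75). Control replicate 4 stood highest for Alas1 (10.72 against 8.78 to 9.14, 0.814) and Alas2 (10.86 against 10.43 to 10.53, 0.767) and lowest for Gadd45b (6.50 against 7.10 to 7.29, 0.759). Control replicate 1 stood lowest for Tet1 (4.40 against 4.80 to 4.91, 0.784) and highest for Tet2 (8.52 against 8.21 to 8.27, 0.806). Control replicate 3 stood lowest for Cyp2c55 (8.60 against 9.39 to 9.69, 0.725) and Pklr (9.32 against 9.82 to 9.97, 0.769). The remaining cases were Elovl6 in phenobarbital replicate 3 (11.95 against 11.05 to 11.31, 0.711) and Fcgr2b in control replicate 2 (10.41 against 9.94 to 10.07, 0.723).

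Outside the named genes, 10092 probe sets had no symbol or several. Of these 1573 passed limma's adjusted p of 0.05, 13 at least 2-fold higher and 64 at least 2-fold lower in treated animals. The largest rise in a probe set of unknown gene went from a mean of 4.65 to 9.78 (log2 fold change 5.13, 5.19 within the labelling batch). Under the batch block 8 of the 10 largest rises kept their call and none of the 10 largest falls did (adjusted p from 0.126 to 0.95). Among those falls the largest went from -2.05 to -0.11, and another reversed from -1.61 to 0.08.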

How the results depend on the processing

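The batch block and spike-in covariate were chosen after seeing the data; the other alternatives were planned. Where a cause is not named, the cause was not tested. Dim genes lie near background, which limits what can be called among them; the count of called genes was 2636 among the brighter genes (9098 tested), 3328 with single-transcript probe sets, 4412 with array weights and 2431 to 4610 with 1 animal left out (lowest without phenobarbital replicate 2, then 2460 without control replicate 2, highest without control replicate 4). At 2-fold it was 96 to 128 with 1 animal left out. Medians then ranged from 0.101 to 0.154 for lipogenesis, 0.04 to 0.077 for other oxidases and 0.029 to 0.137 for cholesterol synthesis. Tested singly, 8425 probe sets passed (400 at 2-fold), from 45037 tested. The replicate numbers did not pair the animals (correlations of same-numbered deviations -0.02 to 0.12), and the replicate block gave 3664 genes, 110 at 2-fold.

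The batch block gave 143 and 65 genes and the covariate 129 and 59. Median log2 fold changes under the block were 0.004 for other oxidases and hydrolases and 0.037 for lipogenesis, both now past camera, and -0.132 for periportal and -0.16 for fatty acid oxidation genes, no longer past it; the covariate gave 0.037, 0.037, -0.162 and -0.116. Lists past camera in neither fit also changed the sign of their median under the block, among them cholesterol synthesis (-0.132), the unfolded protein response (-0.07) and gluconeogenesis (0.062). Under the block 46 named genes stayed on their side of the threshold and 89 lost their call, in part from the wider errors of a single control. Uncalled genes can change sign among the 46, as Cyp7a1 (-0.50), Slc5a2 (-0.23), Tet3 (-0.07) and Dnmt1 (-0.09) did; the called genes that reversed were Mvd (-0.034, and -0.156 with the covariate), Fdps (-0.104) and Ass1 (0.036), with Cyp4a14 under the covariate (0.0324). Single-transcript probe sets reversed Ighm (-0.15) and Fcgr2b (0.17).

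Among the brighter genes P450 electron transfer (0.142), other oxidases (0.052), lipogenesis (0.182) and cholesterol synthesis (0.066) passed camera, as did unfolded protein response (0.108) and heat shock genes (0.272), and periportal genes (-0.161) did not; these also lost it with the mean of probe sets (-0.146). Lipogenesis passed with trend (0.127), array weights (0.131) and without some animals. With an estimated correlation the calls of conjugating enzymes (0.196), NRF2 targets (0.242), periportal (-0.158) and fatty acid oxidation genes (-0.204) were lost, and with fry P450 electron transfer (0.142), other oxidases (0.051) and imprinted genes (0.076) passed, as did nuclear receptors (-0.044), hepatocyte (-0.027), lymphocyte (0.08) and muscle markers (0.1), while sinusoidal endothelium (-0.192) lost its call.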

Other observations

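Of the tests below, the lists and the count over other splits of the animals were planned; the tests of the labelling batch, of phenobarbital as the sole cause, of other cells and of feeding were chosen after the results were seen. The batch tests were also changed once: they first used the position of control replicate 4 between the other controls and the treated animals, and after those values were seen they were replaced by the number of calls kept with the batch as a block, which rests on the same single control. Genes for plasma proteins of the acute phase moved both ways. Orm2 and Orm3, orosomucoids, rose by 2.41 ± 0.15 and 2.42 ± 0.12 (SE), 2.42 and 2.44 within the labelling batch, while the receptor gene Il6ra fell by 1.90. Of 28 members 5 were higher and 2 lower by both adjustments, over all genes and adjusted over the list alone, with a median log2 fold change of -0.04 against a mean of 0.05 and a camera direction upward (adjusted p = 0.827; downward with the batch as a block, median -0.18, adjusted p = 0.177). Genes more abundant in female mouse liver, which male animals express weakly, were higher in 8 and lower in 2 of 20 members, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0139). That call was lost with an estimated correlation (adjusted p = 0.679), without control replicate 4 (camera adjusted p = 0.103) and among the brighter genes (median -0.10). The list passed camera with the batch as a block (median 0.28 against 0.24) but not with an estimated correlation there. The block rests on control replicate 4, whose list mean of 5.56 was the lowest of all arrays (5.71 to 6.06 in the other controls). Cyp2b9 rose by 4.14, the stem cell marker Prom1 by 2.44 and Cyp2b13 by 1.94 (5.26, 2.68 and 1.49 within the batch, where Cyp2b13 did not pass), and several members also belong to the P450 list. Male-biased genes had 1 higher and 3 lower of 20 by both adjustments (camera adjusted p = 0.351).

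Immediate-early and heat shock genes, which answer handling and stress, were higher in 7 and lower in 1 of 25, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.121, but 0.0334 and 0.0277 without phenobarbital replicate 2 or 3, and 0.0127 among the brighter genes). Phenobarbital replicate 1 had a list mean of 9.04 against 8.10 to 8.48 in the other treated animals and 7.94 to 8.41 in controls, and the list's median went from 0.19 to as little as 0.075 with 1 animal left out. Its median was 0.12 with the batch as a block (camera adjusted p = 0.509). Unfolded protein response genes had 2 higher and 1 lower of 26, and none adjusted over the list alone (camera adjusted p = 0.203, but 0.0451 among the brighter genes, and the median went from 0.12 to -0.07 with the batch as a block and to as little as 0.03 with 1 animal left out). Clock genes had 3 lower and none higher of 18 by both adjustments (camera adjusted p = 0.421). Foetal liver and tumour markers had 2 higher and 2 lower of 15 by both adjustments, with Prom1 and Ly6d higher and Lgr5 and Golm1 lower (camera adjusted p = 0.913). In the remaining cell type lists, camera adjusted p lay between 0.251 and 0.975, and fry, which does not compare a list with other genes, passed lymphocyte (0.0299) and muscle markers (0.0302). The lymphocyte list had Ighm as its called member, 1 of 13 measured (1.65, but -0.15 on a probe set that matches a single transcript). Pancreas markers had 3 higher of 10, muscle markers 1 of 9 or 2 adjusted over the list alone, cholangiocyte markers 1 of 11 and erythroid markers 1 of 5, all others by both adjustments. Limma called none of the 9 neutrophil, 10 kidney and 6 adipose markers, and 0, 0 and 1 of them had an unadjusted p under 0.05.

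The first pattern is the large number of small changes. Of 100 splits drawn from the 126 possible of the 10 animals into 5 and 5 only the real 1 gave as many called genes, 3692 against at most 451 in the others. At least 2-fold, 109 genes were called against at most 15 in the others. The 3583 calls under 2-fold exceed the 451 calls of any size in the other drawn splits. That argues against chance for the number of small and of larger calls, not for any single gene. A split into the 4 and 6 arrays of the labelling batches, which shares all but 1 array with the real split, called 3696 genes, 2560 of them the same. The counts of 3692 and 3696 therefore do not tell the treatment from the batch. Splits that swap control replicate 4 for a treated array keep the 4 other controls together. They were not counted apart from the other splits and would rest on control replicate 4 alone. Of the 69 genes at least 2-fold higher, 47 kept their call with the batch as a block, with a median log2 fold change of 1.54 before and 1.56 after, which argues against the batch as the whole cause of these rises. Of the 3583 calls under 2-fold 69 were kept, and of the 40 genes at least 2-fold lower 8, while 3508 and 38 kept their sign. Over the calls under 2-fold, which mix rises and falls, the signed median log2 fold change went from -0.24 to -0.10 and does not give their size. Over the larger falls it went from -1.23 to -0.83. The median ratio to the value without the block was 0.684 and 0.678 in that order. The median standard error rose from 0.09 to 0.14 and from 0.22 to 0.32. Calls thus ended from smaller values, from wider errors, and from an adjustment over genes that is stricter when fewer genes pass. In the simulation with a batch effect and 200 genes changed, the block recovered 79.0% of 2-fold and 25.5% of 1.4-fold changes. Far more genes were called here, so these shares do not set how many calls to expect. The count kept cannot decide on the batch for the calls under 2-fold or the larger falls. The block leaves control replicate 4 as the only control in the comparison. When each control was left out of the fit in turn, control replicate 4 lay 0.528 of the way from the other controls to the treated animals over the calls under 2-fold, against -0.11 to 0.236 for the other 4 controls, a range of 0.35. By the first criterion that value, below 1 by more than this range, had counted against the batch as the whole cause, a reading withdrawn because it rests on a single animal. The calls kept with the block rest on that animal as well, so the reading for the 69 rises carries the same limit. Over the falls of at least 2-fold control replicate 4 lay at 0.543, against -0.35 to 0.126 for the other controls. Over the rises of at least 2-fold it lay at 0.067, against -0.11 to 0.115. A mixture of phenobarbital with the batch, or with that animal's own state, may account for the small changes and the larger falls. These causes cannot be told apart because 1 control alone shares the treated arrays' batch.

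The second pattern is the rise of Meg3 and Rian. Of their 10 called probe sets 8 were also called with the batch as a block, with a mean rise of 1.93 over all controls and 1.55 over control replicate 4, which lay 0.48 above the other controls (SD of all controls 0.25), which argues against the batch as the whole cause. That reading too rests on control replicate 4 as the single control of its set. The probe sets measure Meg3 and Rian alone, on the same arrays, so they are not separate pieces of support. More stellate or endothelial cells, a possible source of imprinted RNA, would raise those cells' markers, whose median log2 fold changes were instead -0.18 and -0.19. Lower markers speak against more of these cells, not against a rise of the RNA within them. An effect of phenobarbital on the cluster, in hepatocytes or in other cells, is a hypothesis left open. Which cells carry the RNA was not tested. Of the cluster's genes Mirg and Dlk1, looked up after the result was seen, Mirg was called higher on 1 of its 2 probe sets (0.51), a call lost with the batch as a block (0.41), and Dlk1 on none.

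The third pattern is the fall of fatty acid oxidation genes. With the batch as a block limma kept 0 of its 16 lower members, with a median log2 fold change of -0.45 before and -0.26 after. Left out of the fit, control replicate 4 lay 0.377 of the way to the treated animals over the 17 members then called lower. The other controls, each over the members called without it, lay from -0.80 (control replicate 2) to 0.344. By the first criterion, being above all of these, control replicate 4 had counted for the batch. The criterion in use leaves the batch open. It cannot decide here, because the block leaves control replicate 4 as the only control in the comparison. The median standard error of the 16 members rose from 0.09 to 0.15. In the simulation with a batch effect and 200 genes changed the block recovered 25.5% of 1.4-fold changes. Far more genes were called here, so that share does not set how many of the 16 to expect. A difference in feeding before sacrifice could give the same fall: 15 genes known to rise on fasting, outside the list, had a median log2 fold change of -0.25, with 4 called lower (Pck1, Irs2, Ppargc1a and Klf10) and 1 higher (Asl), several of them known to have fallen when the test was written, which neither meets nor excludes what feeding predicts. The batch, feeding and phenobarbital cannot be told apart for these genes, since 1 control shares the treated arrays' batch and phenobarbital itself may change the fasting genes.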
